A study of Drosophila ananassae with 15 samples.

How the data were processed

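RNA was measured in 15 libraries from hemocytes of Drosophila ananassae, 5 per group. Per the labels' protocols, cytosol was taken from single cells through a patch pipette (whether 1 cell or several went into a library is not given), polyA RNA was used and libraries were made with the Illumina Nextera XT kit, which cuts and tags DNA and does not record the strand. The submitters' processing notes name STAR, a spliced read aligner. Its version, the genome build, the annotation and the counting step are not given in the sources used here. The authors deposited raw counts per gene, whole numbers without normalization, in a single table of 15978 gene IDs and 92 ERCC spike-in entries. ERCC spike-ins are synthetic RNAs added in known amounts. They held 5 counts over all libraries, 1.11e-05% of the total, and were kept out of library sizes and tests. Of the gene IDs, 2794 were never counted.

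Each of the 15 columns matched 1 sample title, and groups were taken from the labels. The table gives FlyBase IDs without gene names. The reference table used here, of assembly ASM1763931v2 with 16982 genes, shared no identifier with them, so 0 IDs were matched and genes are given by ID only. For that reason the 31 gene lists fixed in advance, among them markers of plasmatocytes and other hemocyte types, had 0 matched members, and no list could be tested. Genes that share reads with near-identical copies or that overlap on either strand could not be marked, and GC content and gene length were not analysed here.

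Genes were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10, which left 6874. Library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit with robust dispersion, glmQLFTest) was fitted to all 15 libraries with group as the only term, and 3 contrasts between groups were tested in R 4.3.3. A gene was called at an adjusted p (Benjamini-Hochberg) of 0.05. CPM values use the TMM-scaled library sizes, and standard errors were derived from the quasi-likelihood F statistic. For a gene with no counts in a group, a bound was computed from a floor of 3 counts over the summed libraries of that group. With 983925 to 4402042 counts per library, that floor came to 0.102 CPM in plasmatocytes, 0.171 CPM in giant hemocytes and 0.415 CPM in uninduced cells.

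Library totals, detected genes and the share of the most counted gene were compared by exact two-sided permutation tests of 5 against 5 libraries, adjusted over 12 tests, with a smallest possible p of 0.00794. Spearman correlations between libraries used log CPM with a pseudocount of 1 over 8145 genes with at least 50 counts in total. Counts were not thinned for them, so differences in depth can affect them. The difference in counts between libraries of one group was measured by a chi-square per degree of freedom over genes with at least 20 counts in the pair.

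The rule for named genes was fixed before the data were examined. Among called genes whose 5 libraries of one group all lay to one side of the other 5, and with a mean of at least 1 CPM in a group, it took the genes with the smallest p. Without gene names, only its part for unnamed genes applied, the 2 rising and 2 falling of each comparison. FBgn0251820 and the sets of the 10 most abundant genes were chosen after the values were seen.

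The tests were run on simulated counts drawn from the means and library sizes of the 6874 genes, with 100 genes changed by 4-fold and 100 by 16-fold. With a spread shared by all groups, the fit for giant hemocytes against plasmatocytes recovered 7% of the former and 34% of the latter and called 1 unchanged gene. The spread of the real groups differed, so the simulation was repeated with a spread for each group. There the fit of all 15 libraries called 77 unchanged genes among 133 calls for giant hemocytes against plasmatocytes, 50 among 102 for plasmatocytes against uninduced cells and 0 among 25 for giant hemocytes against uninduced cells. The fit of only the 2 groups compared called 1 among 10, 26 among 59 and 5 among 88. For giant hemocytes against plasmatocytes it recovered 0% of the 4-fold and 9% of the 16-fold changes, where the fit of all 15 libraries recovered 11% and 45%. Each setting was a single draw. The share of unchanged genes among calls depends on how many genes change, so it does not carry over to the real calls.

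Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, no count filter or a stricter one, fits of only the groups compared, dispersion without robust estimation, counts thinned to 983925, the 10 most counted genes left out, the title number as a block, and each library left out in turn. A voom fit with a variance per group, the summing of uninduced libraries 1 with 2 and 3 with 4, and the thinning of counts without the most counted gene, were added after seeing the data.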

Results

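The series measured polyA RNA in blood cells (hemocytes) of the fly Drosophila ananassae, 72 h into the experiment per the labels. Its title names the subject as the response of multinucleated giant hemocytes to parasitoids, insects whose young develop inside the body of a host. Giant hemocytes are large blood cells that hold several nuclei, and plasmatocytes are the phagocytic blood cells of flies. The labels give 3 groups of 5 libraries each. Activated plasmatocytes and giant hemocytes came from induced animals, and the uninduced blood cells make up the remaining group. The labels give the uninduced group only as blood cells. In comparisons with it, induction cannot be told apart from cell type or mix. The protocol describes drawing cytosol from single cells with a patch pipette, but the labels do not say whether a library holds 1 cell or several pooled, nor from which animals. All p-values therefore measure only the spread between these libraries, which may be technical, and some libraries may share animals.

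Gene counts per library summed to between 983925 and 4402042. The mean total was 3678510 ± 604652 (SD, n = 5) in plasmatocytes, 3177960 ± 734243 (SD, n = 5) in giant hemocytes and 2129400 ± 914240 (SD, n = 5) in uninduced blood cells. Plasmatocyte totals exceeded uninduced totals in an exact two-sided permutation test (p = 0.0159, adjusted p = 0.0273 over a family of 12 tests). No difference of giant hemocyte totals passed the same exact test (p = 0.27 against plasmatocytes and p = 0.0873 against uninduced cells). Intervals and floors given for these counts cover counting error only, since the reads carried no stated molecular identifiers.

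The 3 cell populations differed in how many genes were detected. A plasmatocyte library had at least 1 count for 4884.2 ± 944 gene IDs (SD, n = 5), a giant hemocyte library for 6369.6 ± 518 and an uninduced library for 10144.8 ± 1456. After every library was thinned to 983925 counts, the means were 4643.4 ± 880, 6041.2 ± 452 and 9248.4 ± 875. At that equal total giant hemocytes exceeded plasmatocytes by 1397.8 genes (exact permutation p = 0.0159, adjusted p = 0.0273). The difference from uninduced cells was −4605 genes for plasmatocytes and −3207.2 for giant hemocytes, each with the smallest p that 5 against 5 libraries allow (exact permutation p = 0.00794, adjusted p = 0.0238). Equal totals leave unequal counts for other genes where a single gene dominates a library. With the most counted gene left out and all libraries thinned to 195742 remaining counts, an alternative added after seeing the data, the means were 4302 ± 779 in plasmatocytes, 5184.6 ± 380 in giant hemocytes and 7659.2 ± 65.1 in uninduced cells (SD, n = 5). The difference of giant hemocytes minus plasmatocytes was then 882.6 genes (exact permutation p = 0.0476, adjusted p = 0.0476 over 3 tests), and those from uninduced cells were −3357.2 for plasmatocytes and −2474.6 for giant hemocytes (exact permutation p = 0.00794, adjusted p = 0.0119).

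A single gene ID, FBgn0251820, took 2.40% to 80.1% of the counts of a library. It was singled out after the values were seen because it was the most counted. Its mean share was 43.0% ± 21.6 (SD, n = 5) in uninduced cells, 20.3% ± 22.9 in plasmatocytes and 9.7% ± 12.2 in giant hemocytes. Its level fell in giant hemocytes against uninduced cells (log2 fold change −3.13, SE 1.07, edgeR adjusted p = 0.0385). That call was lost on leaving out giant hemocyte library 1, 4, 5 or 6 or uninduced library 1, 2, 3 or 5, with an edgeR adjusted p of 0.0553 to 0.114. It was not called in giant hemocytes against plasmatocytes (log2 fold change −1.30, adjusted p = 0.412) or in plasmatocytes against uninduced cells (log2 fold change −1.83, adjusted p = 0.199) in the same edgeR test. Without plasmatocyte library 3, where it took 60.5% of the counts, it fell in plasmatocytes against uninduced cells (log2 fold change −3.78, edgeR adjusted p = 0.00241).

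**Figure D1:**
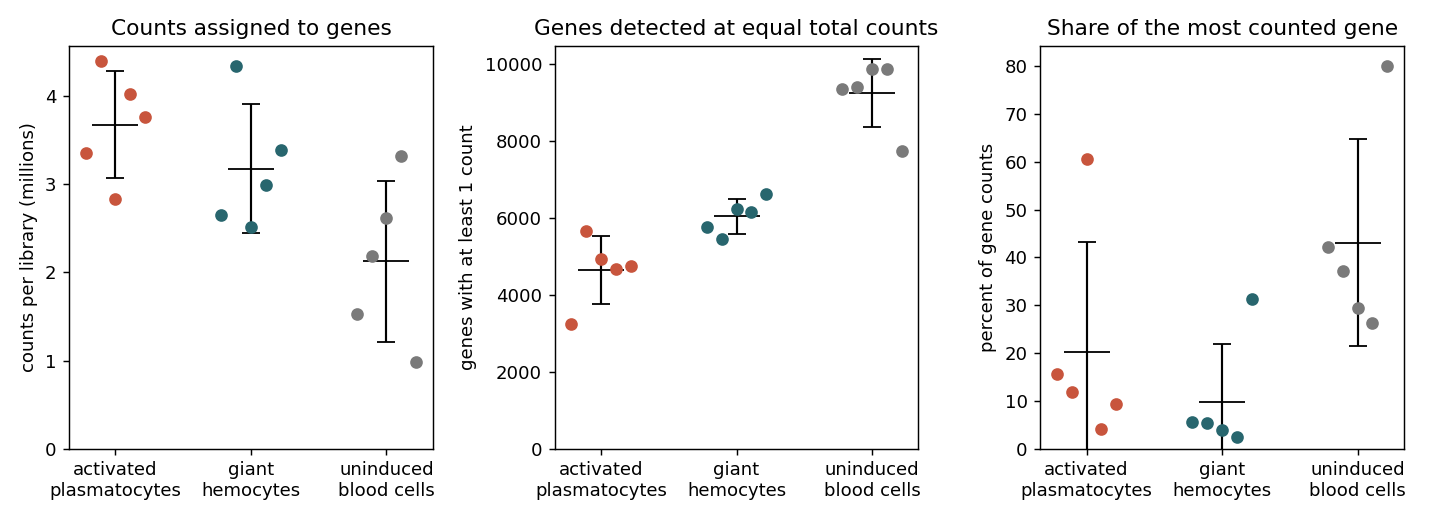
Points are the 15 libraries and bars the mean ± SD of each group of 5; a bar that would pass below 0 ends at the axis. The panels plot total gene counts, genes with at least 1 count after thinning to 983925 counts, and the percent of counts from FBgn0251820, and the lowest uninduced library, in which FBgn0251820 took 80.1% of the counts, detects 7746 genes at equal total against at most 6631 in any induced library.

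Uninduced libraries stood apart from induced ones, and giant hemocyte library 7 lay closer to the plasmatocytes than the other giant hemocyte libraries did. Across 8145 genes, which are not independent replicates, the mean Spearman correlation was 0.829 between uninduced libraries, 0.808 between giant hemocyte libraries and 0.659 between plasmatocyte libraries. It was 0.559 between plasmatocyte and giant hemocyte libraries, 0.35 between plasmatocyte and uninduced libraries and 0.298 between giant hemocyte and uninduced libraries. The biological coefficient of variation estimated within each group was 1.76 in plasmatocytes, 0.997 in giant hemocytes and 0.462 in uninduced cells. Pairs of a plasmatocyte with a giant hemocyte library ranged from 0.481 to 0.582 without giant hemocyte library 7, below the 0.604 to 0.739 within plasmatocytes, and from 0.612 to 0.734 with it. Giant hemocyte library 7 had a mean correlation of 0.680 with the plasmatocyte libraries, against 0.516 to 0.553 for the other 4 giant hemocyte libraries and 0.614 to 0.692 for plasmatocyte libraries with the rest of their own group. With the other 4 giant hemocyte libraries its mean correlation was higher, at 0.763. Uninduced libraries 1 and 2, and libraries 3 and 4, correlated at 0.945 and 0.967, above the 0.725 to 0.857 of the other 8 uninduced pairs. Their chi-square per degree of freedom was 4.49 and 3.25, above counting noise, against 42.3 to 165 for the others. Libraries made from the same cells or RNA could also exceed counting noise, and the labels do not say whether the close pairs share cells. They were counted as the 5 samples the labels give, and summing each pair left 167 falling genes in giant hemocytes against plasmatocytes and 575 rising genes in giant hemocytes against uninduced cells, where the 5 libraries gave 301 and 915.

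**Figure D2:**
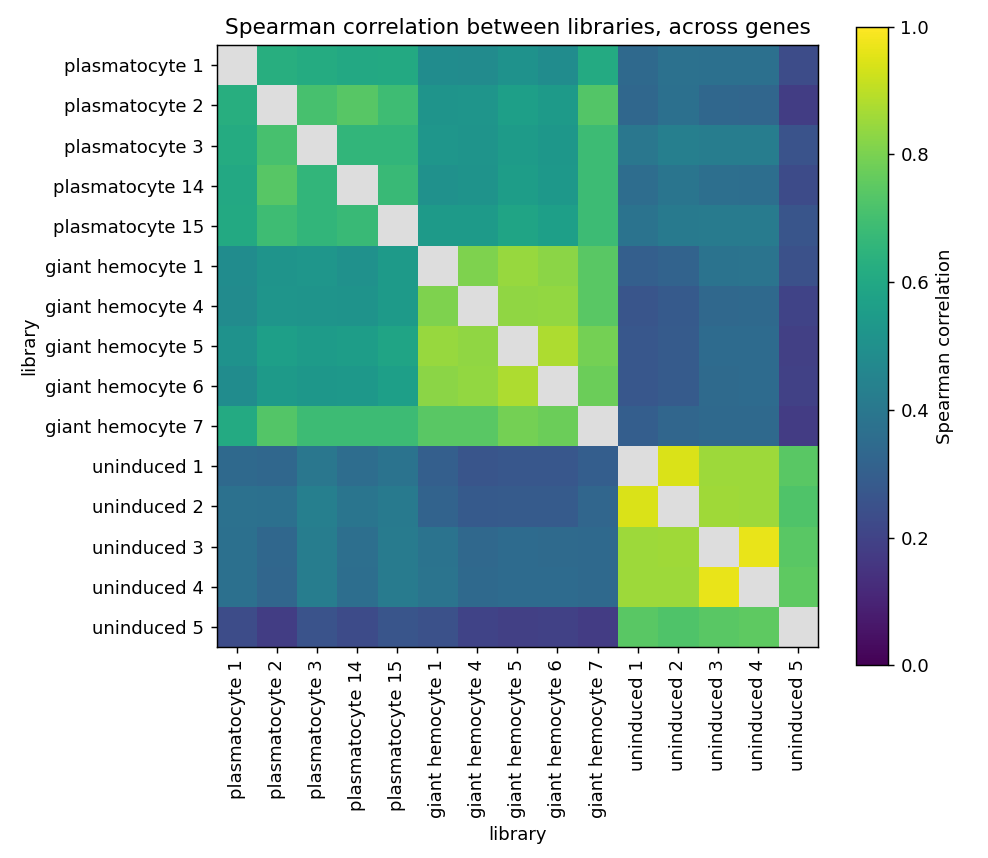
Each cell gives the Spearman correlation of 2 libraries across 8145 genes, on a colour scale from 0 to 1, with the diagonal left grey. The uninduced block averages 0.829 and the giant hemocyte block 0.808, while giant hemocyte library 7 also reaches a mean of 0.680 with the plasmatocyte libraries.

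The first comparison asked how giant hemocytes differ from activated plasmatocytes of induced animals at the same time. Genes higher in giant hemocytes than in plasmatocytes made up much of the giant hemocyte RNA: 853 genes rose and 301 fell among 6874 tested, by edgeR's quasi-likelihood test at an adjusted p of 0.05. The rising genes supplied 46.6% ± 12.9 (SD, n = 5) of giant hemocyte counts, 8.51% ± 3.53 of plasmatocyte counts and 3.36% ± 1.21 of uninduced counts. Their share was 24.2% in giant hemocyte library 7 and 48.9% to 56.6% in the other giant hemocyte libraries. Shares of called genes, here and below, were measured in the libraries that called them. Their direction between the 2 groups compared therefore follows from the choice of genes. The falling genes supplied 1.92% ± 0.892 of giant hemocyte counts, 12.8% ± 4.92 of plasmatocyte counts and 4.66% ± 1.65 of uninduced counts. Called without giant hemocyte library 4, 5 or 6, the falling genes supplied 1.04% to 1.13% of giant hemocyte counts, 8.45% to 9.16% of plasmatocyte counts and 2.48% to 2.95% of uninduced counts, and called without giant hemocyte library 1 or uninduced library 4 they supplied 18.3% or 3.08% of uninduced counts. The 10 most abundant giant hemocyte genes other than FBgn0251820, a set described after the values were seen, gave 19.1% ± 6.15 of the giant hemocyte counts, 1.73% ± 1.07 in plasmatocytes and 0.157% ± 0.112 in uninduced cells. All 10 rose against plasmatocytes under each of 3 scalings, a direction favoured by choosing them for their level in giant hemocytes. RLE and upper-quartile factors shifted this comparison's median by only 0.0133 and −0.0523, so the other scalings add little.

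The larger change of rising than of falling genes rested mostly on giant hemocyte library 7, which lay toward the plasmatocytes. The median log2 fold change of the rising genes was 5.01, or 4.58 with genes absent from a group placed at the bound that 3 counts allow, and that of the falling genes was −2.80. Without giant hemocyte library 7 they were 5.03 and −4.87, or 4.57 and −4.42 with absent genes at their bound. With each of the other libraries left out in turn, the falling median ran from −2.50 to −3.61. The rising median ran from 4.92 to 6.11, or from 4.38 to 5.06 with absent genes at their bound. No counts in any plasmatocyte library were seen for 282 of the rising genes, and none in any giant hemocyte library for 28 of the falling ones. These numbers became 337 and 173 without giant hemocyte library 7. The 282 became 293 to 495 with any library left out, highest without plasmatocyte library 2 or 3 (495 or 466). Among these were 293 to 339 without an uninduced library, a group outside this comparison. Without plasmatocyte library 1, 2, 14 or 15 the 28 became 54 to 74. Fits with a library less tested 7053 to 7482 genes, so these numbers are not for the same set of genes. The median level of all called genes was 59.0 CPM (counts scaled to a common library total) in giant hemocytes and 1.18 in plasmatocytes for the rising set, and 20.3 against 117 for the falling set. The 5 libraries of one group lay entirely to one side of the other 5 for 586 rising and 160 falling genes. Such separation was found for 14.9% of the genes tested, where chance gives 0.794%. Counted as detection alone, 153 gene IDs were present in all 5 giant hemocyte libraries and no plasmatocyte library, and 0 showed the opposite pattern. Other splits of the 10 libraries gave at most 36 genes of either pattern (exact permutation p = 0.00794). Without giant hemocyte library 7 the numbers were 191 and 32, where other splits of the 9 libraries gave at most 131 (exact permutation p = 0.00794), and without plasmatocyte library 2 they were 271 and 0.

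Of the individual genes, FBgn0092703 stood at 232 CPM ± 63.7 (SD, n = 5) in giant hemocytes with 0 counts in every plasmatocyte library, at least 2266-fold higher than the floor of 3 counts over the group (edgeR adjusted p = 2.39e-05). It averaged 5.02 CPM in uninduced cells. FBgn0091276 rose from 112 CPM ± 32.8 in plasmatocytes to 1186 CPM ± 406 in giant hemocytes (log2 fold change 3.41, SE 0.33, edgeR adjusted p = 2.39e-05), with 914 CPM in uninduced cells. FBgn0091485 fell from 202 CPM ± 38.3 to 21.7 CPM ± 17.3 (log2 fold change −3.21, SE 0.49, edgeR adjusted p = 0.000421), and giant hemocyte library 7 held the highest value of its group at 52.6 CPM. FBgn0088555 fell from 8.0 CPM ± 5.55 to 1 count in 1 giant hemocyte library (edgeR adjusted p = 0.000402). The plasmatocyte level was 145 times the giant hemocyte level, with a 95% exact counting interval from 25.8 to 5753, and uninduced cells held 379 CPM. Of the 243 plasmatocyte counts 126 came from library 14, and library 15, with 2 counts (0.304 CPM), was close to the 0.299 CPM of giant hemocyte library 7.

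The number of calls depended on the fit. Of these 2 groups alone, a fit that also tested fewer genes (5228) called 389 rising and 128 falling, whereas voom with a variance per group called 1208 and 314, with 812 of the 1154 genes shared. In data simulated with a separate spread for each group, the fit of all 15 libraries made 133 calls of which 77 were unchanged genes, against 1 of 10 for the fit of 2 groups, which recovered 9% of the 16-fold changes against 45%. Without giant hemocyte library 7 the falling genes numbered 628, and without giant hemocyte library 4, 5 or 6 they numbered 189, 164 or 173, and without plasmatocyte library 1 they numbered 456.

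The second comparison set activated plasmatocytes of induced animals against uninduced blood cells. More genes fell than rose: 1374 fell and 730 rose among 6874 tested (edgeR, adjusted p of 0.05). The falling genes made up 31.8% ± 11.9 (SD, n = 5) of uninduced counts and 3.55% ± 1.29 of plasmatocyte counts. The rising genes made up 30.7% ± 9.76 of plasmatocyte counts, 2.67% ± 1.19 of uninduced counts and 47.1% ± 8.26 of giant hemocyte counts. Called without plasmatocyte library 3, the falling genes included FBgn0251820 and made up 76.3% of uninduced and 14% of plasmatocyte counts, and called without uninduced library 5 they made up 6.14% of plasmatocyte counts. Of the falling genes, 590 had no counts in any plasmatocyte library, whereas 5 of the rising genes had none in any uninduced library. The 590 became 621 to 1175 with any library left out. Among these were 832 to 904 without a giant hemocyte library, a group outside this comparison. Fits with a library less tested 7053 to 7482 genes rather than 6874, so these numbers are not for the same set of genes. The 5 became 4 to 9 over all libraries left out in turn. The median log2 fold change was −7.25 over the falling genes, or −6.48 with absent genes at their bound, and 2.70 over the rising genes, or 2.69 with absent genes at their bound.

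The 10 most abundant uninduced genes other than FBgn0251820, described after the values were seen, supplied 19.5% ± 8.78 (SD, n = 5) of uninduced counts, 1.02% ± 0.178 of plasmatocyte counts and 0.428% ± 0.194 of giant hemocyte counts. In edgeR's test 9 of the 10 fell in plasmatocytes, and 9 fell in giant hemocytes. Choosing them for their level in uninduced cells favoured that direction. By detection alone, 1257 gene IDs were present in all 5 uninduced and no plasmatocyte library, and 8 showed the opposite pattern, where other splits gave at most 83 of both (exact permutation p = 0.00794). Without uninduced library 5 the 1257 became 2143, and without plasmatocyte library 1 the 8 became 17. The 5 libraries of one group lay to one side of the other 5 for 1248 falling and 565 rising genes, a separation seen for 34.7% of the genes tested where chance gives 0.794%.

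Among individual genes, FBgn0098709 rose from 20.1 CPM ± 4.68 in uninduced cells to 497 CPM ± 114 in plasmatocytes (SD, n = 5; log2 fold change 4.62, SE 0.31, edgeR adjusted p = 1.95e-07), and FBgn0091533 rose from 17.0 CPM ± 5.57 to 497 CPM ± 81.1 (log2 fold change 4.85, SE 0.35, edgeR adjusted p = 2.57e-07). FBgn0091449 fell from 9927 CPM ± 1307 to 1393 CPM ± 326 (log2 fold change −2.83, SE 0.24, edgeR adjusted p = 1.27e-06). FBgn0087189 averaged 923 CPM ± 240 in uninduced cells and had 0 counts in all 5 plasmatocyte libraries, at least 9025-fold lower at the floor of 3 counts over the group (edgeR adjusted p = 1.51e-06). It also had 0 counts in all 5 giant hemocyte libraries.

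The balance of directions moved with the scaling. The median log2 fold change of all tested genes was −0.52 with TMM factors and −1.18 with RLE factors, a shift of −0.67, and the RLE factors gave 524 rising and 1788 falling genes. Leaving out the 10 most counted genes gave 600 rising and 2003 falling, and in data simulated with a separate spread for each group 50 of 102 calls for this comparison were unchanged genes.

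The third comparison set giant hemocytes against uninduced blood cells. Giant hemocytes differed in both directions: 915 genes rose and 1191 fell among 6874 tested (edgeR, adjusted p of 0.05). The rising genes accounted for 59.0% ± 12.1 (SD, n = 5) of giant hemocyte counts, 27.1% ± 8.52 of plasmatocyte counts and 3.25% ± 1.38 of uninduced counts. The falling genes, which include FBgn0251820, accounted for 78.9% ± 8.20 of uninduced counts and 13.3% ± 12.5 of giant hemocyte counts. The other 1190 falling genes accounted for 35.8% ± 13.7 and 3.59% ± 0.754. Called without giant hemocyte library 1, 4, 5 or 6 or uninduced library 1, 2, 3 or 5, which ended the call of FBgn0251820, the falling genes made up 32.8% to 43.1% of uninduced and 3.06% to 4.57% of giant hemocyte counts, and called without giant hemocyte library 7 they made up 7.93% of giant hemocyte counts. The median log2 fold change was 3.13 over the rising and −6.33 over the falling genes, or 3.12 and −6.06 with absent genes at their bound. No giant hemocyte library held counts for 380 of the falling genes, and no uninduced library for 10 of the rising ones. The 380 became 400 to 829 with any library left out. Among these were 586 to 624 without a plasmatocyte library, a group outside this comparison. Fits with a library less tested 7053 to 7482 genes, so these numbers are not for the same set of genes. The 10 became 10 to 18 over all libraries left out in turn. The 10 most abundant giant hemocyte genes described above all rose here as well, under each of 3 scalings, a direction again favoured by their choice.

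Presence in all 5 uninduced and no giant hemocyte library was seen for 963 gene IDs and the opposite for 20, where other splits gave at most 104 of both (exact permutation p = 0.00794), and without uninduced library 5 the 963 became 1683. The groups did not overlap for 837 rising and 1116 falling genes, and for 43.8% of the genes tested, where chance gives 0.794%. FBgn0098709, named above for plasmatocytes, reached 1228 CPM ± 163 (SD, n = 5) in giant hemocytes (log2 fold change 5.92, SE 0.33, edgeR adjusted p = 8.93e-09). FBgn0099185 rose from 24.6 CPM ± 10.3 to 1664 CPM ± 382 (log2 fold change 6.06, SE 0.39, edgeR adjusted p = 2.03e-08), with 523 CPM in plasmatocytes. FBgn0091449 fell to 1136 CPM ± 199.6 (log2 fold change −3.13, SE 0.24, edgeR adjusted p = 1.5e-07). FBgn0087779 fell from 5607 CPM ± 1284 to 153 CPM ± 55.2 (log2 fold change −5.20, SE 0.41, edgeR adjusted p = 1.51e-07), with 336 CPM in plasmatocytes. RLE factors shifted the median of all genes by −0.66 from −0.29 and gave 639 rising and 1582 falling genes, and leaving out the 10 most counted genes gave 723 and 1714. A fit of these 2 groups alone called 1389 rising and 1903 falling genes, and summing the close uninduced pairs into single libraries left 575 rising.

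**Figure D3:**
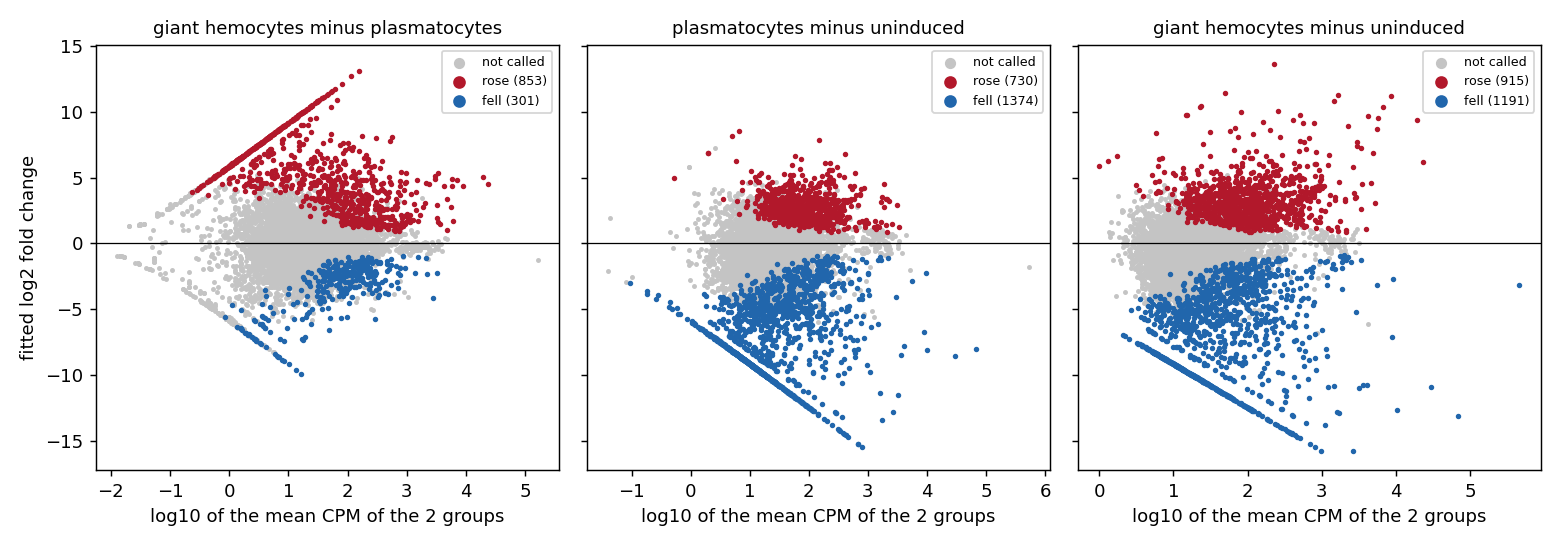
Each point is a gene tested and counted in at least 1 of the groups shown, with log10 of the mean CPM of both groups on the x axis and the fitted log2 fold change on the y axis, red for genes that rose and blue for genes that fell at an adjusted p of 0.05. The straight outer edges are genes with no counts in one group, whose fitted value is no measured fold; 853 genes rise and 301 fall in the first panel, 730 and 1374 in the second, and 915 and 1191 in the third.

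Both induced cell populations shared part of their difference from uninduced cells. Whether induction or a different mix of cells lies behind it cannot be told apart in this design. Of the genes called, 522 rose and 747 fell in both, and 32 were called in opposite directions. Independent lists of these sizes would share 97.2 rising and 238 falling genes. Groups simulated as unchanged against the same uninduced libraries shared 0 called genes in 20 draws, which says little, since unchanged genes are rarely called. When lists as long as the real ones were taken from those draws by p, 345 to 389 rising and 462 to 527 falling genes were in both. Those draws gave all groups the same spread, whereas the spread of the real groups differed. They therefore cannot say what overlap or correlation the shared libraries alone would give here. When the uninduced libraries were split so that each comparison used different ones, over 20 arrangements 254 to 344 genes rose in both and 537 to 569 fell in both. Most arrangements put the 2 libraries of a close uninduced pair on opposite sides. The split overlap and correlation may therefore still carry shared controls. Log2 fold changes of the 6874 genes correlated at 0.70 across genes, against 0.52 in the simulation, with a covariance of 8.99 against 0.744, a difference of 8.25. With split controls the mean correlation was 0.68.

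The genes separating the induced cell types fell into several classes by their level in uninduced cells. Of the 853 genes higher in giant hemocytes than in plasmatocytes, 331 had risen in giant hemocytes over uninduced cells, 472 were not called in that comparison and 50 had fallen. In plasmatocytes 469 of the 853 had fallen against uninduced cells, 104 had risen and 280 were not called. The overlap of 331 compared with 114 for independent lists, 163 to 234 with the giant hemocyte libraries split between the comparisons, and 243 to 302 in equally long lists of unchanged simulated groups. That of 469 compared with 171, with 176 to 329 when plasmatocyte libraries were split, and with 473 to 516 in simulated lists. That of 104 compared with 90.6, 47 to 117 and 6 to 25. Of the 301 genes lower in giant hemocytes than in plasmatocytes, 167 had fallen in giant hemocytes against uninduced cells, compared with 52.2 for independent lists, 11 to 63 with split libraries and 193 to 223 in simulated lists. In plasmatocytes 74 of the 301 had risen over uninduced cells, compared with 32.0, 21 to 54 and 86 to 120, while 33 had fallen, compared with 60.2, 30 to 113 and 9 to 22, and 194 were not called. The classes of 469, 167 and 74 genes thus lay below the overlap of simulated lists of these lengths. That simulation gave all groups the same spread, unlike the real groups, so no conclusion is drawn from it.

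**Figure D4:**
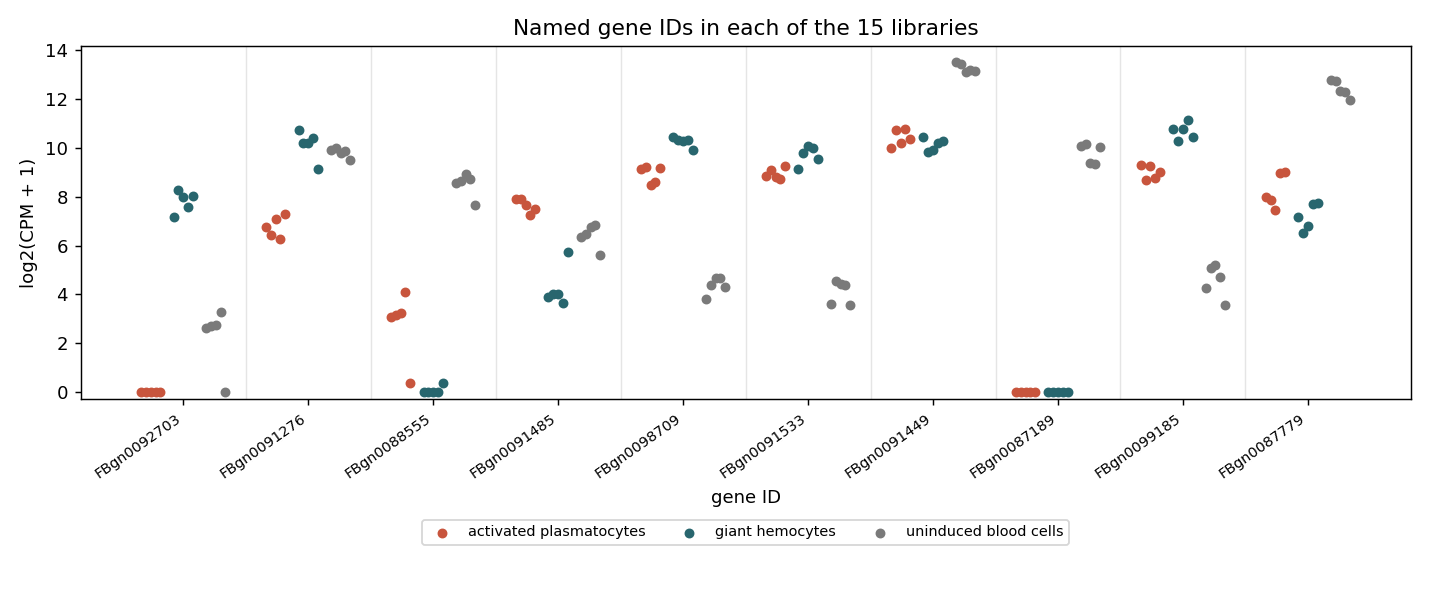
Values are log2(CPM + 1) of the 10 gene IDs named by the rule fixed in advance, with 1 point for each of the 15 libraries. FBgn0092703 is at 0 in all plasmatocyte libraries, FBgn0087189 is at 0 in all 10 induced libraries, and FBgn0098709 and FBgn0099185 are highest in giant hemocytes and lowest in uninduced cells.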

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

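Both tests of explanations in this part were written down before the values they measure were seen, while the comparison with library 7 kept out of the references was added after. Across 54 sets of 5 libraries, 11 had a highest or lowest library whose gap to its neighbour was large for the range of the set. Chance marks about 1 set in 20 where values spread normally, a rate that does not hold for very low counts. Sets with the same value in all 5 libraries could not be marked. The sets are not independent, since several describe the same library.

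Giant hemocyte library 7 stood apart in 5 of these. Its mean Spearman correlation with plasmatocytes was 0.680, where the other 4 giant hemocyte libraries lay at 0.516 to 0.553. FBgn0251820 took 31.3% of its counts against at most 5.54% in the others, and the 10 most counted genes took 40.6% against at most 26.8%. FBgn0091485 stood at 52.6 CPM against at most 15.4, and FBgn0088555 at 0.299 CPM, a single count, where the others had 0.

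For the position of library 7 between the groups, a plasmatocyte library carrying the wrong label was argued against. Of 191 genes counted in all 4 other giant hemocyte libraries and no plasmatocyte library, library 7 held 80.1%, above the 13.6% to 43.5% of left-out plasmatocyte libraries, or 11.6% to 40.5% with library 7 kept out of the choice of genes. Compared alike, with genes and means from 3 giant hemocyte libraries and library 7 in no reference, it held 74.0% to 77.7% of such genes and the other 4 held 72.9% to 92.7%. Plasmatocyte RNA mixed into library 7 stays open: the plasmatocyte fraction was 0.397 by plasmatocyte-high genes and 0.585 by giant-high genes. Compared alike, these were 0.389 to 0.411 and 0.559 to 0.592 in library 7, and −0.00412 to 0.00299 and 0.0015 to 0.187 in the other 4. The fractions of library 7 differ by −0.188 with a 95% bootstrap interval over genes from −0.236 to −0.117, which was set beforehand to exclude a mixture, but that bound ignores the spread between libraries: the interval also excluded 0 in 2 of the 4 others, whose differences averaged −0.0915 (SD 0.104). No biological explanation was tested, since the design holds no group for it.

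Uninduced library 5, the shallowest, stood apart in 3 sets. It detected 7746 genes at equal total, where the other 4 detected 9355 to 9878, but FBgn0251820 took 80.1% of its counts. With that gene left out and the remaining counts thinned to the same number, it detected 7745 genes and the other 4 detected 7573 to 7697. Its mean Spearman correlation was 0.232 with plasmatocytes, where the others had 0.362 to 0.394, and 0.742 with the other uninduced libraries, where the others had 0.845 to 0.856. These correlations were not recomputed at equal counts. Outside FBgn0251820 it held 195742 counts, against 883351 to 2448562 in the other 4. In plasmatocyte library 3, FBgn0251820 took 60.5% of the counts and the 10 most counted genes 63.9%, against at most 15.6% and 22.8% in the other 4. Giant hemocyte library 1 had a mean Spearman correlation of 0.327 with the uninduced libraries, where the others had 0.286 to 0.297. Outside the genes, the ERCC spike-in entries held 5 counts in 3 libraries of induced animals and 0 in the uninduced libraries.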

How the results depend on the processing

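The alternatives here that were chosen after seeing the data are the voom fit with a variance per group, the summing of close uninduced libraries and thinning without the most counted gene. Under that thinning the differences in detected genes kept their direction and an exact permutation p below 0.05. For giant hemocytes minus plasmatocytes that p was 0.0476, adjusted over 3 tests only, where the main family held 12. The rule named genes with the smallest p in these same counts, which favoured stable calls, so their stability says little about other calls. Named genes kept their direction and their side of the threshold in all 335 alternative values computed for the 12 results of genes named by rule. FBgn0251820 did not: its fall in giant hemocytes against uninduced cells was lost in 9 of 27 alternatives, 8 of them with a library left out (adjusted p from 1.08e-05 to 0.114 over all alternatives). Against uninduced cells it was called in plasmatocytes by DESeq2, by both voom fits and without plasmatocyte library 3 (adjusted p from 0.00241 to 0.484 over all alternatives). In giant hemocytes minus plasmatocytes its log2 fold change turned from −1.30 to 0.66 without that library and ranged down to −2.61 with others left out, never called. Leaving out each library in turn, giant hemocytes minus plasmatocytes gave 904 to 1598 calls, 731 to 1025 rising and 164 to 628 falling genes. Plasmatocytes minus uninduced cells gave 1881 to 2674 calls, 618 to 851 rising and 1259 to 1932 falling, and giant hemocytes minus uninduced cells gave 1816 to 2848 calls, 740 to 1128 rising and 1052 to 1720 falling. Fits with a library less tested 7053 to 7482 genes, because the filter uses the smallest group. For falling genes of the first comparison, the highest count came without giant hemocyte library 7 (628), and counts moved by over 1.5 times also without plasmatocyte library 1 (456) and giant hemocyte libraries 4 (189), 5 (164) and 6 (173); the cause was not tested. RLE and upper-quartile scaling, the stricter filter, dispersion without robust estimation, thinning and leaving out the 10 most counted genes kept each count of the 3 comparisons within 1.5 times.

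Giant hemocytes minus plasmatocytes, with 1154 calls, gave 1856 calls with 662 falling by DESeq2, 1864 with 1333 rising and 531 falling by voom with quality weights, and 517 with 389 rising and 128 falling when only these 2 groups were fitted. Summing the close uninduced pairs left 167 falling. Plasmatocytes minus uninduced cells, with 2104 calls, gave 2152 falling by DESeq2, 3241 calls with 2561 falling by voom with quality weights, 3251 with 2628 falling by voom with a variance per group, and 6520 with 5713 falling without a filter. Giant hemocytes minus uninduced cells, with 2106 calls, gave 1975 falling by DESeq2, 4317 calls with 1511 rising and 2806 falling by voom with quality weights, and 3952 with 1407 rising and 2545 falling by voom with a variance per group. It gave 5339 calls with 4332 falling without a filter, 3292 with 1389 rising and 1903 falling when only these groups were fitted, and 575 rising with the uninduced pairs summed. Without a filter 13184 genes were tested; the cause of the other changes was not tested. Split controls lowered the genes rising in both induced groups to 294.35 on average from 522, and RLE scaling to 353, while RLE raised those falling in both from 747 to 1028.

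The numbers in the titles showed no clear pairing of the samples, though 7 pairs are too few to exclude it. Libraries with the same number deviated from their group means with correlations of −0.0781 to 0.112 over these 7 pairs, against −0.119 to 0.226 for different numbers. With the title number as a replicate block, which leaves fewer degrees of freedom, the first comparison gave 278 calls (171 rising, 107 falling), the second 895 (300 rising, 595 falling) and the third 1116 (499 rising, 617 falling).

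The tests of gene lists and their alternatives were not run, because 0 list members were matched to the gene IDs. Depth limits the uninduced libraries most: 3 counts over the group correspond to 0.415 CPM there, against 0.102 in plasmatocytes.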

Other observations

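Both tests of why more genes rose than fell were chosen after the result was seen. The loss of abundant messages could be followed by level. Of 903 gene IDs at 100 CPM or more in uninduced cells, 63 had no counts in any plasmatocyte library, 83 had none in any giant hemocyte library, and 40 had none in any of the 10 induced libraries. Of 4276 gene IDs at 1 to 10 CPM in uninduced cells, 2042 had no counts in any plasmatocyte library and 1593 had none in any giant hemocyte library.

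Fewer genes were detected in induced than in uninduced libraries. The totals of the induced libraries were the higher ones on average, so lower depth was not among the explanations. Random loss of transcripts during library making, at 1 rate for all abundant genes, was argued against. Plasmatocyte genes of 100 CPM or more were missed in 0.988% of library values. Applied to each library independently, that rate would put 8.48e-08 genes at 0 in all 5 libraries, where 63 were. A gene lost from most libraries cannot reach that level, so a loss that differs between genes stays open. For the 2042 genes under 10 CPM random loss cannot be told apart from a true difference. The loss rate of 54.9% gives 213 such genes, but a level this low is only seen in libraries that kept the gene, so the bound set beforehand rested on a rate that is too low, and a loss of 86.3% per library would account for all. In giant hemocytes the same rate was 36.2%, which gives 26.4 genes where 1593 were absent, and a loss of 82.1% per library would account for all. That lies further from random loss, under the same limit. Also open is the number and mix of cells behind each library, which was not tested, and the difference between induced and uninduced cells that the design names.

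More genes rose than fell in giant hemocytes against plasmatocytes. Random loss in the plasmatocyte libraries was tested on genes at 100 CPM or more in either group. Plasmatocyte genes of that level were missed in 0.988% of plasmatocyte values, a rate that leaves out genes lost from most libraries. Of the calls there, 368 rose and 165 fell, so 69.0% rose, with 62.3% to 75.0% when each library was left out in turn. Of the 368 rising genes, 238 were counted in all 5 plasmatocyte libraries. These alone outnumber the 165 falling genes, which argues against complete loss as the whole cause when all libraries are used. Without giant hemocyte library 7, 404 such genes rose and 244 fell. How many of those 404 were counted in all 5 plasmatocyte libraries was not computed, so the argument was not made without that library. With all libraries, the remaining rising genes were missing from at least 1 plasmatocyte library, a pattern that loss would also leave. The wider spread of the plasmatocyte libraries stays open as a cause. With a variance per group 79.4% of calls rose (1208 rising, 314 falling), with 72.4% to 83.3% when each library was left out. The fit of the 2 groups alone gave 389 and 128. Neither fit can decide. The former uses log counts, where a wider spread lowers the mean of a group, and the latter shares 1 spread between its groups. A lower recovery of plasmatocyte RNA short of complete loss was not tested, and a biological difference between the cell types stays open.

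Chance assignment of libraries to groups was argued against for the number of calls in each comparison, with each library taken as independent. The close uninduced pairs may share cells, which limits this for both comparisons with uninduced cells. Among 100 of the possible splits, the real one, counted as 1, was the only split with as many calls. The real split called 1154 genes against 170 for the next highest between giant hemocytes and plasmatocytes, which exchanged giant hemocyte library 7 for plasmatocyte library 1. It called 2104 against 3 between plasmatocytes and uninduced cells, with 1 split as large, and 2106 against 3 between giant hemocytes and uninduced cells, again with 1.

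Genes that rose in giant hemocytes over plasmatocytes stood next to each other in the table more often than by chance. Of adjacent tested entries, 107 pairs both rose, against a mean of 65.0 and at most 94 in 10000 shuffles of the order (permutation p = 1e-04, the smallest they can give). The longest run held 5 genes. For genes that fell, 14 adjacent pairs lay within the 95% range of 3 to 14 of the shuffles (one-sided permutation p = 0.03). As a hypothesis, neighbouring genes may rise together in giant hemocytes. Whether the order of the table follows the genome is not given in the sources used here, and reads shared by overlapping or duplicated neighbours were not tested.

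Giant hemocyte libraries were also placed by genes called without library 7 and without 1 of the other 4, with the mean of the remaining 3 as reference, a comparison chosen after the values were seen. Library 7 lay between that mean and the plasmatocyte mean for 67.5% to 68.7% of rising and 88.4% to 89.6% of falling genes. The other 4 libraries, placed by the same genes and means, did so for 43.3% to 49.5% of rising and 32.0% to 45.5% of falling genes.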
